A study of Arabidopsis thaliana with 12 samples.

How the data were processed

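Total RNA of wild-type Arabidopsis thaliana, ecotype Wassilevskija, was measured on an expression array in 12 samples, 6 from plants given 100 mM proline for 48 h and 6 labelled as water, which the labels also describe as untreated. The labels give no tissue, age or growth conditions, and nothing in them says that the samples came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

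The authors deposited 1 table of processed values with 3439 probes and 12 columns. The deposited values are relative intensity on a linear scale, between 0 and 61.4, and this was read from the values themselves. The scanner, the dyes, the background correction, the normalization between arrays and the reference to which the values were scaled are not given in the sources used here. Of all deposited values, 8.43% were exactly 0 and none was negative. The medians of the values above 0 lay between 0.0325 and 0.0963, so the columns were not on 1 common level. Scanner files were not analysed here, and signal over background could not be computed. The number of arrays limits the precision.

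Probe names came from a platform annotation table, which can be old. Of the 3439 probes, 692 had 1 gene, 870 had several genes and 1877 were not listed with a gene. The 692 probes stood for 691 loci, updated through gene identifiers to the names of the TAIR10.1 assembly, and 2 of the 692 identifiers were not in that gene table and kept the array's name. No gene was named from a probe with several genes. No coordinates are given, because the table names no genome build.

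Values of 0 were treated as missing, and the others were log2-transformed. Because the array medians differed by more than 0.1, the log2 values were quantile normalized between arrays, and probes of the same locus were averaged. A feature is either a locus or a probe without a single gene. Features with at least 4 values in each group were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0), with no covariate and Benjamini-Hochberg adjustment, and a call was an adjusted p under 0.05. The 393 features with fewer values were left out of the test. Fold changes are proline against water, and log2 values are on the scale of the quantile-normalized relative intensity. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

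Before the data were examined, the test, its threshold, the other settings to be tried, 19 gene lists and the rule for naming genes were fixed. The lists held 313 loci of proline metabolism, other amino acid and nitrogen metabolism, photosynthesis, stress responses, secondary metabolism, ribosomal proteins, reference genes, and markers of root and seed. The rule named every measured gene of proline metabolism, the 12 loci with the largest increase and the 12 with the largest decrease among calls with a single locus name, and from each other list up to 2 called members in each direction or, where none was called, the member with the smallest p. Only 7 loci of these lists were measured under a single name. No fixed list reached the 5 measured members set for a list test. A further 6 lists were therefore made from the gene names on the array. They were chosen after the names, the brightness and the deposited values of PSAN, SBPASE and PRK had been seen, and before any gene was tested. Lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and with fry. For these list tests a missing value was filled with the mean of its feature in its group, which narrows the spread within groups.

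The samples were compared with each other before the test. For all 12 samples, the nearest sample of the same group was the partner in the pairs numbered 1 and 2, 3 and 4, or 5 and 6. These pairs are called sets 1, 2 and 3. The median absolute log2 difference was 0.23 to 0.40 between the partners of a set and 0.485 to 0.815 between samples of the same group in other sets. The deposited values of partners were not identical, and their Pearson correlation across features on the log2 scale was 0.829 to 0.920, against 0.781 to 0.879 between samples of the same group in other sets, so these ranges overlap. Features are not independent replicates. The limma test takes the 12 samples as independent, and fits that respect the sets were added after seeing the data: the set within its group as a random block (duplicateCorrelation, estimated correlation 0.593), the mean of each set as 1 sample, and the set as a fixed block.

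The fits were tested on simulated data with 3045 features, 20 runs per setting, and 200 changed features where an effect was simulated. With a correlation of 0.593 within sets and no effect, the test on 12 independent samples made 7.35 calls per run on average (22 at most), and the random block made 0.1. With 200 changed features and the same correlation, 33.7% of the calls of the test on independent samples and 6.85% of those of the random block were false. The first recovered 44.1% of the changes of 1 log2 unit and 77.3% of those of 2, and the random block recovered 17.4% and 58.7%. With the set means as samples, 0.7% and 28.8% were recovered. The simulation drew set effects separately in each group, at the correlation the random block had estimated, and drew features independently. This is the model of the random block itself, so its low share of false calls was built in. Set effects shared by water and proline were not simulated.

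The other settings fixed beforehand were other normalizations between arrays, the replicate number as a block, a filter on dim features, complete values only, each sample left out in turn, other variance settings, single probes, 2 stricter thresholds, and the settings of the list tests. The planned offset before the log, the 5th percentile of the values, was 0 and could not be used. An offset of 0.01 with zeros kept was added in its place.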

Results

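The series compared wild-type Arabidopsis thaliana of the ecotype Wassilevskija after 48 h with 100 mM proline, an amount meant to raise cellular proline to a toxic level, with plants on water. Relative messenger RNA levels of 3439 array probes were read in 6 samples per group. The question was which transcripts differ when proline accumulates. The median deposited intensity of the values above 0 was 0.0759 to 0.0812 in water and 0.0957 to 0.0963 in proline in set 1 (samples 1 and 2), 0.0758 to 0.0780 and 0.0678 to 0.0698 in set 2 (samples 3 and 4), and 0.0325 to 0.0335 and 0.0335 to 0.0345 in set 3 (samples 5 and 6).

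Transcripts of CML41 (AT3G50770), a calmodulin-like calcium-binding protein, rose 7.91-fold with proline (log2 change 2.98 ± 0.41, SE, n = 6 and 6, adjusted p = 0.00174 with limma). Transcripts of AT4G32060, an EF-hand protein of mitochondrial calcium uptake, rose 2.78-fold, those of AT1G67800, a member of the copine family, 2.81-fold, and those of AT5G55580 (mTERF9), of a family of organellar transcription factors, 3.02-fold. Among the decreases, AT3G11150 fell 11.2-fold, AT5G11550, an armadillo-repeat protein, 5.82-fold, and AT5G19940, of the plastid fibrillin family, 4.43-fold. In all, 401 of 3045 tested features passed the threshold, of which 168 rose and 233 fell. Of these calls, 64 were loci with a single name, out of 608 tested, and 27 of them rose and 37 fell.

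The changes had the same direction in all 3 sets for 396 of the 401 calls (98.8%), but the calls were selected by a test over these same sets, which favours such features, so this is no independent check. The median fold was 2.49 among the features that rose and 2.22 among those that fell, and 128 and 160 of them changed at least 2-fold. The median log2 change over all tested features was -0.16. It was also -0.16 over the features with a value in all 12 samples, and -0.02 with zeros kept and an offset of 0.01. The features with all values came from the same normalization, which left zeros out. Their median is therefore no separate check on the zeros. The share of calls that rose was 41.9% after quantile normalization, 62.6% with arrays centred on their median (214 of 342), 54.1% with cyclic loess (224 of 414), 54.2% with zeros kept (249 of 459) and 85.0% with no normalization between arrays (17 of 20), so the balance of increases and decreases was not settled by these data.

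Because partners within a set resembled each other more than other samples of their group, the 12 samples could not be taken as independent. If each set repeats a measurement of the same material, the p-values above are too small. If the sets are batches shared by both groups, the direction of the error is not settled. With the set as a fixed block and partners taken as independent, 783 features passed. With the set as a random block in limma, 82 features passed, 35 higher and 47 lower with proline, and all 82 were among the 401. With the mean of each set as 1 sample (3 against 3), none of 3269 features passed in limma, the smallest adjusted p was 0.0941, and 472 had an unadjusted p under 0.05, compared with 591 in the random block and 939 in the test on 12 samples. Set 2 weighed most: without it 29 features passed, and 6 with the random block. Without set 3 these counts were 193 and 9, and without set 1 they were 589 and 223. Leaving out water sample 3 or water sample 4 gave 245 and 248 calls.

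Of the 12 named loci with the largest increases and the 12 with the largest decreases, 7 also passed with the random block. These were CML41 (adjusted p = 0.0109), AT4G32060 (0.0391), AT1G67800 (0.0410), AT5G55580 (0.0451), AT3G11150 (0.0391), AT5G11550 (0.0391) and AT5G19940 (0.0391). No locus passed with the set means as samples. CML41 rose by a log2 change of 2.24 in set 1, 2.21 in set 2 and 4.50 in set 3. AT4G32060 was higher by 1.15, 1.67 and 1.60 in the same order, and AT5G19940 was lower, with log2 changes of -1.20, -3.13 and -2.11. AT3G11150 had a value above 0 in 4 of 6 proline samples, as had AT4G03150 and AT4G23110 among the other decreases, so these folds leave out samples listed at 0. CML41 was also the single locus of these 24 that passed with no normalization between arrays and without set 2, where its adjusted p was 0.0128 and 0.0229. Over all alternatives its adjusted p ran from 6.67e-05 to 0.203.

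The other 8 of the 12 largest increases passed in the test on 12 samples and not with the random block. They were AT2G23160 (4.54-fold), AT2G30100 (4.38-fold), FBL17 (3.87-fold, 5 values per group), an F-box protein of the cell cycle, AT1G35510 (3.32-fold), of the O-fucosyltransferase family, AT4G24930 (3.01-fold), a protein of the thylakoid lumen, AT1G24530 (2.99-fold), AT3G56810 (2.93-fold) and AT5G46560 (2.93-fold). AT1G24530 was listed at 0 in proline sample 5, so its fold leaves out a sample that goes against the increase. Its log2 change in set 3, 0.372, rests on proline sample 6 alone. Of these 8, AT2G30100 varied most between the sets, with log2 changes of 0.26, 3.39 and 2.74. The adjusted p of these 8 loci lay between 0.0166 and 0.0463, and with the random block between 0.0585 and 0.175.

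Among the 12 largest decreases, 9 passed in the test on 12 samples and not with the random block. AT3G50180 fell 7.68-fold and AT3G50130 fell 3.93-fold, and both belong to a plant protein family of unknown function. AT3G18870, a second member of the mTERF family, fell 6.57-fold, opposite to AT5G55580. AT1G09200, which encodes histone H3.1, fell 3.46-fold, and its probe may also read the near-identical copies of this gene. AT2G32040, of a family of folate and biopterin transporters, fell 3.36-fold. The remaining 4 were AT1G02020 (4.66-fold), AT4G03150 (4.51-fold), AT2G36480 (3.74-fold) and AT4G23110 (3.40-fold). With the random block the adjusted p of these 9 loci was 0.0722 to 0.273. The mean brightness of 10 of the 24 loci, taken over both groups, was below the middle of the tested features. Among them were the decreases that passed with the random block, AT3G11150, AT5G11550 and AT5G19940, at percentiles of 30.4, 42.4 and 22.1. The increases that passed with it lay at percentiles of 65.1 to 93.8. A fall lowers the mean over both groups and a rise raises it, so this difference is in part built in. In water alone the mean log2 values of AT3G11150, AT5G11550 and AT5G19940 were -3.59, -3.209 and -4.255. Those of CML41, AT1G67800, AT5G55580 and AT4G32060 were -4.364, -4.152, -2.92 and -1.025, so the ranges overlap.

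**Figure D1:**
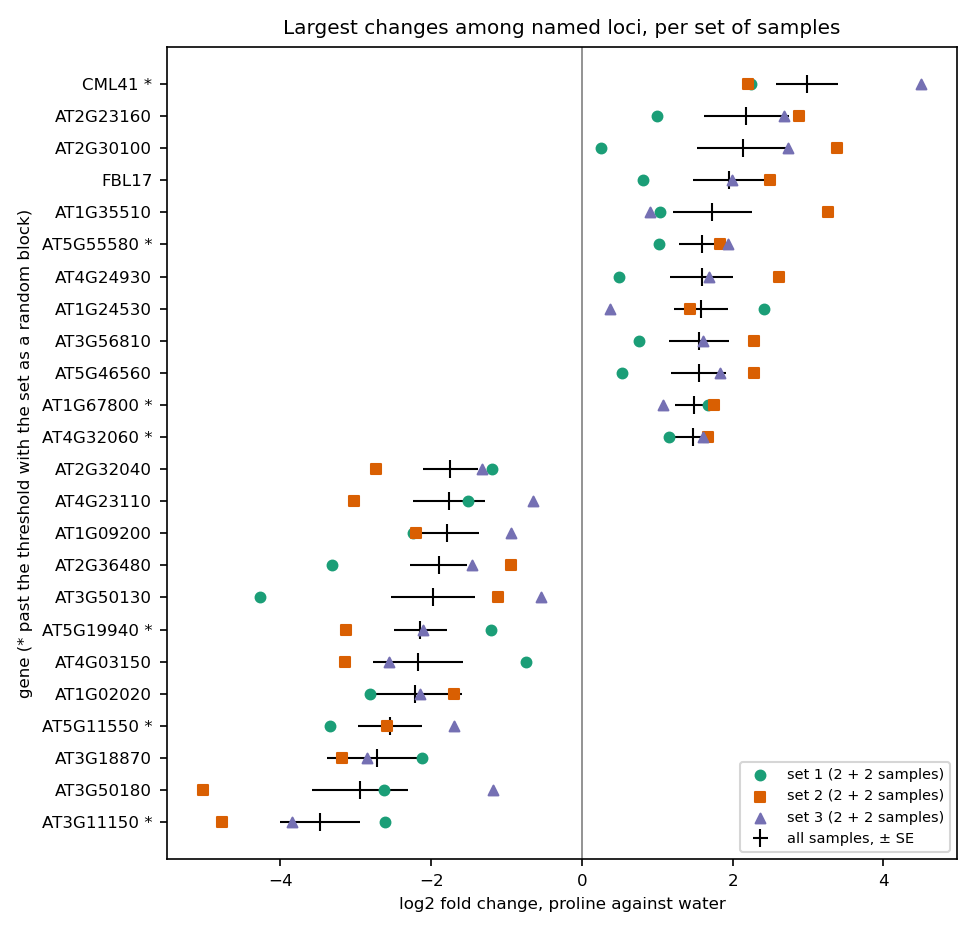
Log2 fold change of the 24 named loci with the largest changes (vertical axis, loci; horizontal axis, log2 of proline over water), with points for sets 1, 2 and 3 (2 samples of each group per set) and a black mark with its SE for all samples. All 24 loci, selected by a test over these sets, have the same direction in the 3 sets, CML41 leads the increases at 2.98, and asterisks mark the 7 loci that also passed with the set as a random block.

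None of the 17 genes of proline metabolism fixed beforehand was measured under a single gene name. They were the enzymes of proline synthesis and breakdown and its transporters. Probes with several genes were not searched for them. Of the 19 lists fixed beforehand, 3 had a measured member, with 7 loci in all. None of the 7 passed in limma over all features, and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 3 of 4 members of the light reactions and 2 of 2 of the Calvin cycle passed, and 0 of 1 of branched-chain amino acid breakdown. These passes were lost when the sets were respected: adjusted over the list alone, none passed with the random block (lowest adjusted p 0.082 in the light reactions and 0.085 in the Calvin cycle) or with set means (0.215 and 0.0941). All 7 are named here, 4 of them outside the naming rule.

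Of the 6 measured photosynthesis genes of the lists fixed beforehand, none passed the threshold over all features; 5 had a log2 change below 0 and 1 above. LHB1B2, a chlorophyll-binding protein of the light-harvesting antenna, had a log2 change of -0.68 ± 0.25 (SE, n = 6 and 6, adjusted p = 0.0924), PSAN of photosystem I -0.81 ± 0.32 (0.105) and PSBY of photosystem II -0.51 ± 0.19 (0.0939). PSBW of photosystem II had a change of 0.49 ± 0.24 in the other direction (0.187), which passed with arrays centred on the median (0.82, adjusted p = 0.0212, the lowest of its alternatives, which reached 1). Among the genes below 0, the adjusted p over all alternatives ran from 0.0448 to 1 for LHB1B2, which passed with the trend and robust setting, from 0.0386 to 0.894 for PSAN, from 0.0458 to 1 for PSBY, which passed without water sample 2, and from 0.0468 to 1 for PRK. SBPASE, the sedoheptulose-bisphosphatase of the Calvin cycle, had a change of -1.16 ± 0.44 (0.0939) and PRK, phosphoribulokinase, -0.56 ± 0.22 (0.101). In set 3 alone LHB1B2, PSAN and PRK were not lower, at 0.045, 0.071 and 0.017. ETFQO, an electron-transfer protein of branched-chain amino acid breakdown, had a change of -0.20 ± 1.2 (adjusted p = 0.931).

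The list of chloroplast photosynthesis and biogenesis had 24 tested members, of which 1 fell, none rose and 23 did not pass. It was made after the names on the array and the deposited values of its members PSAN, SBPASE and PRK had been seen. SECE1, a subunit of the chloroplast Sec translocase, fell by 0.98 on the log2 scale (1.98-fold, adjusted p = 0.0493, and 0.232 with the random block). SECE1 passed in 6 of the 23 settings fixed beforehand, and not with arrays centred on the median, cyclic loess or no normalization between arrays (0.0307 to 0.677 over all alternatives). The median log2 change of the list was -0.32, and 16 members were below 0 and 8 above. The list did not stand apart from the other features in camera (adjusted p = 0.903, and 0.942 with an estimated correlation). The fry test, which asks whether the members move one way and takes the samples as independent, gave an adjusted p of 0.00053. It does not set the members against all tested features, whose median log2 change was -0.16, and it includes the members whose values had been seen.

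In the list of redox and detoxification, also made after the names were seen, 1 of 5 tested members fell and 4 did not pass. CUTA, a copper-binding chloroplast protein, fell 2.49-fold (log2 change -1.32 ± 0.29, SE, n = 6 and 6, adjusted p = 0.0136, and 0.0475 with the random block). CUTA did not pass with arrays centred on the median (-0.99, adjusted p = 0.108) or with no normalization between arrays (-0.93, 0.147), and its adjusted p ran from 0.00113 to 0.508 over all alternatives. It was among the brighter features, above 97.5% of the others. Adjusted over the list alone in limma, 2 members passed. They were CUTA (adjusted p = 0.003, and 0.00639 with the random block) and GLDH (log2 change -1.36, adjusted p = 0.0484, and 0.063 with the random block). None passed with set means (lowest adjusted p 0.111). GLDH was chosen after its values were seen. Camera gave an adjusted p of 0.903 for this list (0.942 with an estimated correlation) and fry 0.240.

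None of the 7 tested floral and meristem regulators passed over all features, and 3 passed adjusted over the list alone: AGL103, a MADS-box factor (-0.60 ± 0.20, adjusted p = 0.0604, and 0.0137 to 1 over all alternatives), LAS, a GRAS factor of axillary meristems (-0.90 ± 0.30, 0.0608), and TCP15 (0.58 ± 0.20, 0.0750). None of the 3 passed over the list alone with the random block (lowest adjusted p 0.157) or with set means (0.321). AGL103 passed over all features in 5 of the 23 settings fixed beforehand, among them the features with values in all 12 samples (adjusted p = 0.0409). LAS and TCP15 were chosen after their values were seen. Camera gave an adjusted p of 0.934 for it and fry 0.498. None of 6 genes of amino acid, nitrogen and sulfur metabolism passed, with CYN, a cyanase, at 0.14 ± 0.21 (adjusted p = 0.694), and camera gave 0.934 and fry 0.875. None of 4 genes of dehydration and salt passed, with SIS, a salt-responsive gene, at -2.25 ± 0.83 (n = 6 and 5, adjusted p = 0.0913), and none of 3 cell wall genes, with CSLA01, a cellulose synthase-like gene, at -0.33 ± 0.22 (0.337). All of these values come from limma.

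Most of the calls had no single gene name: 96 of 773 tested probes with several genes and 241 of 1664 without a listed gene passed. Among the probes without a single gene name the largest increases were those of probe 2243 (log2 change 3.45, adjusted p = 0.00586, and 0.0722 with the random block) and probe 1126 (3.03, adjusted p = 1.19e-05, and 0.000159 with the random block), and the largest decreases those of probe 4434 (-3.41, adjusted p = 0.0302, and 0.148 with the random block) and probe 3102 (-3.01, adjusted p = 0.00993, and 0.0326 with the random block). Probes 4434 and 3102 had values above 0 in 4 of 6 proline samples and probe 2243 in 5 of 6 water samples, so these folds leave out samples listed at 0. Both proline samples of set 3 were listed at 0 for probe 4434, so no log2 change could be computed there.

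More features were listed at 0 after proline. Water samples had 197.3 ± 35.8 such features (SD, n = 6) and proline samples 382.2 ± 31.8 (SD, n = 6), higher in all 6 proline samples than in any water sample (exact two-sided permutation test over 12 samples, p = 0.00216). Over the 6 set means the exact permutation p was 0.1, the smallest that 3 against 3 allows. Because of the zeros, 209 features had at least 4 values in water and fewer in proline, 37 had the reverse, and neither kind was tested. AT1G29070 and SRX, which encodes the chloroplast enzyme sulfiredoxin, were above 0 in all 6 water samples, at mean intensities of 0.0279 and 0.0223, and listed at 0 in all 6 proline samples. AT1G51110 was above 0 in 6 water samples, at a mean of 0.0155, and in 1 proline sample. No feature showed the reverse. These loci were chosen after their values were seen.

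**Figure D2:**
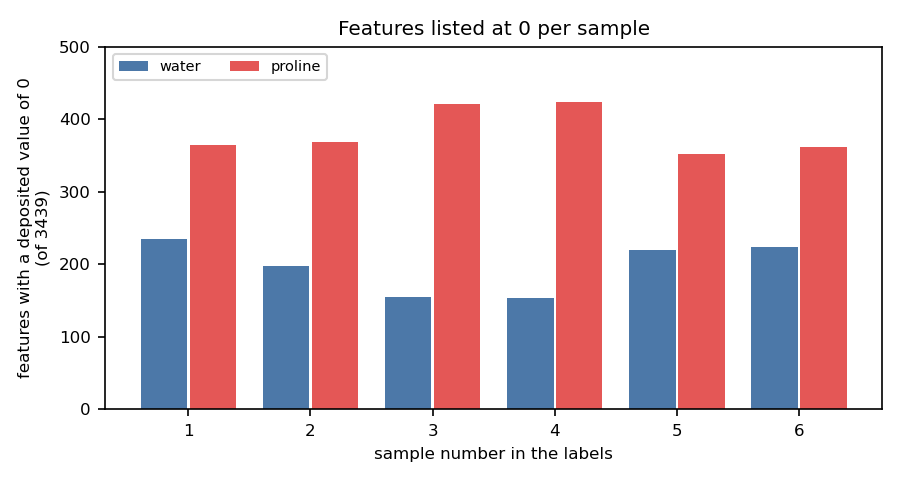
Number of features with a deposited value of 0 (vertical axis, of 3439) in each sample, by sample number in the labels (horizontal axis), with water in blue and proline in red. Water samples have between 153 and 235 such features and proline samples between 352 and 424.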

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

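The test of the sets as repeats of the same material was chosen after its result had been seen. A sample stood apart from the other samples of its group by more than 95% of chance gaps would in 7 of the 88 groups of values tested, and chance gives about 1 in 20. The values are normalized log2 intensities. Water sample 1 lay at -4.84 for AT5G19940 (nearest sample -4.22) and at -3.19 for AT1G13370 (-2.97). Water sample 2 lay at -11.74 for ETFQO (-5.38), near the floor of the values. Proline sample 1 lay at -8.88 for AT1G02020 (-6.04), proline sample 3 at -5.92 for SECE1 (-4.55), proline sample 5 at -7.33 for SBPASE (-4.91) and proline sample 6 at -10.79 for SIS (-6.53). The fold changes of ETFQO, AT1G02020, SECE1, SBPASE and SIS therefore rest in part on 1 sample. Without water sample 2, ETFQO had a log2 change of -1.35 (adjusted p = 0.209; 0.0524 to 1 over its alternatives), against -0.20 with all samples. Without proline sample 6, SIS had a log2 change of -1.28 (adjusted p = 0.0487; 0.0460 to 0.744 over its alternatives).

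The calls between proline and water form the first pattern weighed. Of 100 splits of the 12 samples into 6 and 6, 1 split, the real one with 401 calls, gave as many, and the highest of the others gave 0. This argues against chance labels only if the 12 samples are independent, which could not be assumed. Each other split also mixes water and proline in both groups, so the real contrast adds to the spread within its groups. Only 3 of the other splits drawn kept all 6 sets whole. The splits with calls given next were not drawn, so the highest of 0 depends on the draw. Among the 10 splits of the 6 sets into 3 and 3, grouping water set 1 with proline sets 1 and 2 gave 174 calls and grouping it with proline sets 1 and 3 gave 62 when samples were taken as independent. Each of the 9 splits other than the real one still sets 2 proline sets against 2 water sets, so these calls can hold part of the proline contrast, the structure of the samples, or both. Whether chance labels of whole sets can be excluded is not settled for the 401 calls. With the set as a random block, 1 of these 10 splits, the real one, gave 82 calls and the highest of the others 0; 10 splits are too few for a share under 0.05.

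The 12 of 12 samples whose nearest sample was the partner of their set are in line with each set repeating a measurement of the same material, for example 2 arrays or 2 spots per probe. Sets of separate plants that were grown or hybridised together would give the same value and were not tested apart from it. What stays open for both counts is any technical factor that went with the treatment in all 3 sets, such as the dye, which no source used here gives. An effect of proline itself is also open, as the design names it. The labels give no treatment time for the water samples, and no group was given another solute or nitrogen source. A difference in harvest time or handling, or an effect that any added solute or nitrogen source would have, could therefore not be told apart from proline itself.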

How the results depend on the processing

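The fits that use the sets, and the offset of 0.01, were chosen after seeing the data. Of the results of single genes under the settings fixed beforehand, 763 kept their direction and side of the threshold, 168 lost their call, 10 gained it and 4 changed direction. Under the settings added later these numbers were 327, 308, 8 and 14. All 24 loci with the largest changes kept their direction wherever they were measured. The causes of the differences were not tested except where fewer samples or a stricter threshold set them. The planned offset, the 5th percentile, was 0 and was not run, and the genes of proline metabolism gave no value under any setting. What signal over background limits could not be said from the deposited values.

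Among the 401 calls were 270 of the 342 made with arrays centred on the median, 350 of 414 with cyclic loess, 345 of 459 with zeros kept, and 20 of 20 with no normalization, where 1 of the 24 named loci passed. With zeros kept the median log2 change of all features moved from -0.16 to -0.02. An adjusted p under 0.01 left 76 calls and 8 named loci, and a test against a fold of 1.5 left 19 and 3. Leaving out 1 sample gave 245 to 480 calls and 15 to 23 named loci. Of the 7 members of the fixed lists, where 0 passed, 1 passed with arrays centred on the median, 1 with the trend and robust setting, and 0 to 1 with a sample left out.

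The main test did not pair samples by replicate number. The deviations of same-numbered samples from their group means correlated at 0.187, 0.174, 0.126, 0.136, 0.110 and 0.0966 across features. Among the samples of the other group, 12 of 12 correlated best with the one of their own number. This is a hint of pairing from the data and not from the design. With the replicate block 436 features passed, 325 of them among the 401, and 20 of the 24 named loci. The random replicate block gave 628.

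With the set as a random block 82 calls and 7 named loci remained, and with set means 0 and 0. Set means with the set as a fixed block gave 0 and 0 (585 features at an unadjusted p under 0.05). The set as a fixed block, with partners taken as independent, gave 783 calls and 3 of the 7 list members. Set 1 alone gave 0 calls and 0 named loci (823 at an unadjusted p under 0.05), set 2 alone 321, 8 and 2 list members, and set 3 alone 333 and 11. Each of these takes 2 partners as replicates. Leaving out set 1 gave 589 calls, leaving out set 2 gave 29 calls and 1 named locus, and leaving out set 3 gave 193, 13 and 1 list member. With the random block, leaving out set 1, 2 or 3 gave 223, 6 and 9 calls, with 11, 0 and 0 named loci. The random block gave 80 calls (63 higher, 17 lower) and 10 named loci with arrays centred on the median, and 92 (52 higher, 40 lower) and 8 with cyclic loess.

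The direction changed for genes that were not called. ETFQO had a log2 change of 0.038 without water sample 4, 0.10 without water sample 5, 0.074 without water sample 6, 0.41 without proline sample 5, 3.81 in set 1 alone, 0.45 without set 2 and 1.18 without set 3 (-2.27 without set 1), the same with the random block. CYN was at -0.59 in set 3 alone, -0.0051 without set 1 and -0.074 without set 2 (0.47 without set 3), also with the random block. CSLA01 was at 0.12 in set 1 alone, and LHB1B2, PSAN and PRK were at 0.045, 0.071 and 0.017 in set 3 alone. The list of floral and meristem regulators changed direction with cyclic loess (adjusted p = 0.986) and that of amino acid, nitrogen and sulfur metabolism with fry (0.875).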

Other observations

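The genes in this paragraph were chosen after their values were seen. A second histone H3 locus, AT1G13370, fell by 1.52 on the log2 scale (limma, adjusted p = 0.0101), and with the set as a random block its adjusted p was 0.0626. Its alternatives ran from 0.00245 to 0.480. AT5G10920, which encodes argininosuccinate lyase of arginine synthesis, fell by 1.35 (adjusted p = 0.0355; 0.247 with the random block; 0.0156 to 0.611 over its alternatives). The other 3 loci that passed with the random block were AT1G68660, an adaptor of the chloroplast Clp protease, which fell 2.16-fold (adjusted p = 0.01; 0.0391 with the random block; 0.000773 to 0.477 over its alternatives), AT3G54930, a regulatory subunit of protein phosphatase 2A, which fell 1.96-fold (0.00942; 0.0410; 0.00157 to 0.472), and the protein kinase gene ATSIK, which rose 2.06-fold (0.0114; 0.0467; 0.00256 to 0.508).

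The second pattern weighed is the larger number of features listed at 0 after proline. The tests on array brightness were chosen after the zeros had been seen, and that on their overlap before its result was seen. The zeros were 1.70, 2.74 and 1.61 times as many in proline in sets 1, 2 and 3. By the median and the 75th percentile, dimmer proline arrays are argued against in set 1 alone. There the median of all values, zeros included, was 1.12 times that of water. The 75th percentile was higher too (0.198 to 0.202 against 0.161). In set 2, with the largest excess of zeros, the median was 0.770 times that of water and the 75th percentile was lower (0.160 to 0.165 against 0.167 to 0.177), as dimmer arrays would give. In set 3 the median was 0.949 times that of water and the 75th percentile slightly higher (0.0875 to 0.0883 against 0.0864 to 0.0874), which leaves it open. The 25th percentile was lower in proline in all 3 sets. The mean of all values was higher in proline in all 3 sets (0.444 against 0.322, 0.362 against 0.319 and 0.221 against 0.209). The proline arrays of set 2 were therefore not dimmer throughout. If zeros fell on dim features at random, features listed at 0 in both proline samples of 1 set should share no more zeros with another set than features of like brightness in water. The overlap was 1.46 times this number for sets 1 and 2 (58 against 39.8), 1.37 times for sets 1 and 3 (66 against 48.0) and 1.51 times for sets 2 and 3 (81 against 53.6). In water it was 1.09 to 1.14 times. Brightness was taken from the water samples, zeros included, so zeros in water lower the brightness at which they are compared. The water ratios are therefore no like baseline for those in proline. All 3 ratios in proline were above the lower bound set beforehand, within which random dropout should have kept them. The bound of 1.5 set beforehand against it was not reached in every pair of sets. The result lay between the 2 bounds, so random dropout could not be excluded. A loss of particular transcripts and a background correction that differed between the groups remain possible explanations, and neither was tested.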
